A study of Homo sapiens with 5 samples.

How the data were processed

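RNA of MHH-ES-1 cells was measured on 5 Affymetrix HG-U133 Plus 2 arrays, per the labels' protocols, which give transfection of the mimics with a lipid reagent, total RNA extraction and biotin-labelled cRNA. The deposited values are linear probe set intensity, 1 value for each of 54675 probe sets and each array. The submitters' processing notes name GCOS and Partek without versions or roles, and the signal algorithm is not given in the sources used here. The deposited intensity columns each have a mean of 150 after trimming 2% at each end, so the arrays were scaled to one target before deposit. No detection calls came with the values, so whether a dim probe set lay above background is unknown here.

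Groups were taken from the labels, with 2 arrays each for miR-483-5p and the scrambled control and 1 for miR-483-3p. The 62 control probe sets were left out. The platform annotation used here gives 41097 probe sets with 1 gene symbol, 1801 with several and 11777 with none. Of those with 1 symbol, 41043 matched the RefSeq gene table of assembly GRCh38.p14 through the gene identifier, which was used for names alone. No gene was named from a probe set with several symbols, and the probe sets listed for IGF2, H19 and BBC3 are therefore given by probe set, with all genes they are listed for. NR0B1 has no probe set named here. Each of the 19775 genes with its own probe set was represented by the probe set with the highest mean over all arrays, and 10523 genes had more than 1. Genes whose mean log2 value lay under the 40th percentile of all probe sets, a signal of 27.2, were left out, which left 14591.

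Signals were used as log2(signal + 32) and fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 5 arrays. The fit has 2 residual degrees of freedom, both from the pairs, and 4.96 from the variance prior. Tests were two-sided, with the empirical Bayes moderation of limma and Benjamini-Hochberg adjustment, and a threshold of 0.05. The miR-483-3p group adds no residual degree of freedom. Before the data were examined, 28 gene lists were fixed and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Camera at an estimated correlation tests on the 2 residual degrees of freedom, so a list can lose its call for that reason, whatever its correlation. The estimate was the same in each comparison. It was 0.70 for cholesterol synthesis, 0.46 for G2 and M phase and 0.34 for S phase genes, where the preset of 0.01 assumes far less correlation. For the reported miR-483-5p targets it was -0.046, and for the immediate early list -0.037. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. The genes to be named were also fixed: the 10 highest and 10 lowest per mimic against control, and 5 and 5 between the arms, among genes whose arrays do not overlap, taken first from those past the threshold; the 4 members with the lowest p of each called list; and IGF2, H19, DHX9, BBC3, SRF, MAPK3, SOCS3, CCND1 and NR0B1. CCND1, the cyclin gene of the last group, had a signal of 5881 ± 232 with miR-483-5p, 4459 ± 152 in the control (SD, n = 2 each) and 5019 with miR-483-3p. Its log2 difference between miR-483-5p and the control was 0.40 (limma adjusted p = 0.409), and 0.08 in its second, dimmer probe set.

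On simulated data for miR-483-5p against the control, with 200 of 14591 genes changed, the fit recovered 57.2% of genes changed 2-fold and 98.1% of those changed 4-fold, with 8.35 false calls per simulation over 20 simulations. For miR-483-3p against the control it recovered 18.6% and 94.1%, with 5.85 false calls. In 20 simulations of miR-483-5p against the control, camera called 100% of lists of 30 genes shifted by 0.3 and 5% of unshifted lists. That rate need not hold for the real lists, since splits of the real arrays that balanced mimic and control still gave 6 and 4 called lists. Alternatives were median centring, quantile normalization, no filter and a filter at the 60th percentile, pseudocounts of 1 and 100, the mean of a gene's probe sets, every probe set on its own, a variance prior that follows intensity, other thresholds, and leaving out each of the paired arrays. A block for first arrays against repeats was added after seeing the data. Planned tests of seed sites in 3' untranslated regions were not run, since no transcript sequences were used here. Figures were drawn with matplotlib 3.10.9.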

Results

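Gene expression was measured with Affymetrix 3' expression arrays in MHH-ES-1, an established human Ewing sarcoma cell line, 48 h after transfection with a synthetic microRNA mimic at 50 nM. A mimic is a short RNA duplex that supplies a chosen microRNA to the cell. The mimics carried the 5p or the 3p arm of miR-483, a microRNA hairpin that lies within an intron of the growth factor gene IGF2, or a scrambled sequence as control. There were 2 arrays for miR-483-5p, 2 for the scrambled control and 1 for miR-483-3p. The labels call the second array of each pair a repeat of the first and do not say whether it came from a separate culture, so p-values measure only the spread between these arrays, which may be technical. Median probe set signals were 39.2 and 44.9 for miR-483-5p, 44.4 and 43.2 for the control and 41.9 for miR-483-3p, on arrays that each had a trimmed mean of 150. Across the 14591 genes tested, pairs of arrays correlated at r = 0.977 to 0.983, a correlation across genes, which are not independent replicates. The ratio of the GAPDH probe set at the 3' end to that at the 5' end, a sign of RNA integrity, was 1.09 and 1.10 in the miR-483-5p arrays, 1.02 and 0.996 in the controls and 1.06 in the miR-483-3p array. The same ratio for ACTB was 1.182 and 1.073 with miR-483-5p, 1.065 and 1.040 in the controls and 1.093 with miR-483-3p. By ACTB the second miR-483-5p array and the first control were thus nearly equal. The small number of arrays limits the precision of every value.

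The first comparison asked what the 5p arm changes in these cells, beginning with IGF2, the gene that hosts the microRNA. All 3 probe sets listed for IGF2 were brighter with miR-483-5p than with the scrambled control, and both miR-483-5p arrays lay above both control arrays in each. Probe set 202409_at had a signal of 413 ± 80.8 (SD, n = 2) with miR-483-5p and 197 ± 11 (SD, n = 2) in the control. Probe set 202410_x_at had 97.2 ± 15.8 against 13.1 ± 0.354, and 210881_s_at had 63.1 ± 11.5 against 11.5 ± 2.97. On the log2(signal + 32) scale, which understates the change of dim probe sets, the differences were 0.95 (SE 0.17), 1.52 (SE 0.15) and 1.12 (SE 0.16). The annotation lists each of these probe sets for INS-IGF2, a readthrough gene, as well as IGF2, so the signal is not assigned to one of them. Probe set 202410_x_at had the lowest p of the 14597 genes and shared probe sets tested, and the limma adjusted p-values were 0.281, 0.176 and 0.204, above the threshold of 0.05. With each array centred on its median the adjusted p-values were 0.0441, 0.00181 and 0.0183, and over all alternatives they ran from 0.0296 to 0.518, from 0.00181 to 0.456 and from 0.0183 to 0.518. The probe sets shared by H19 and MIR675, from the neighbouring imprinted gene, differed by 0.15 and -0.10 on the log2 scale, with adjusted p = 0.780 and 0.842.

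Genes reported as targets of miR-483-5p in earlier work were lower with the 5p mimic. Of the 8 genes on that list, 5 fell, SRF rose and 2 did not pass the test when adjusted over the list alone; none passed when adjusted over all genes. The adhesion molecule gene ALCAM had a signal of 463 ± 0.849 (SD, n = 2) with miR-483-5p against 853 ± 43.8 in the control, a fall of 1.79-fold on the log2(signal + 32) scale, and the metalloproteinase inhibitor gene TIMP2 had 1176 ± 6.86 against 2108 ± 49.1, a fall of 1.77-fold. ARHGDIA fell 1.64-fold, the kinase gene MAPK3 fell 1.60-fold and the GTPase gene RHOA fell 1.55-fold. Without the first miR-483-5p array the log2 difference of MAPK3 was -0.44. All 4 probe sets of ARHGDIA gave log2 differences between -0.68 and -0.81, and a second ALCAM probe set gave -1.16. The transcription factor gene SRF was higher by 0.47 on the log2 scale, but its other probe set gave -0.16. The mitochondrial fission gene FIS1 had 604 ± 118 against 769 ± 3.32, and the cytokine signalling inhibitor SOCS3 had 83.5 ± 2.76 against 84.3 ± 5.37. The list median was -0.65 on the log2 scale, and limma's camera, which sets a list against all other genes, called it lower with a preset correlation of 0.01 (adjusted p = 0.000528). The call was lost at adjusted p = 0.869 with an estimated correlation, and fry gave p = 0.0062 and adjusted p = 0.174. The estimated correlation of this list was -0.046, under the preset. The loss therefore goes with the 2 residual degrees of freedom of that test and not with correlated genes. The GAPDH 3' to 5' ratio separated the same arrays, at 1.09 and 1.10 with miR-483-5p and 1.02 and 0.996 in the control.

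**Figure D1:**
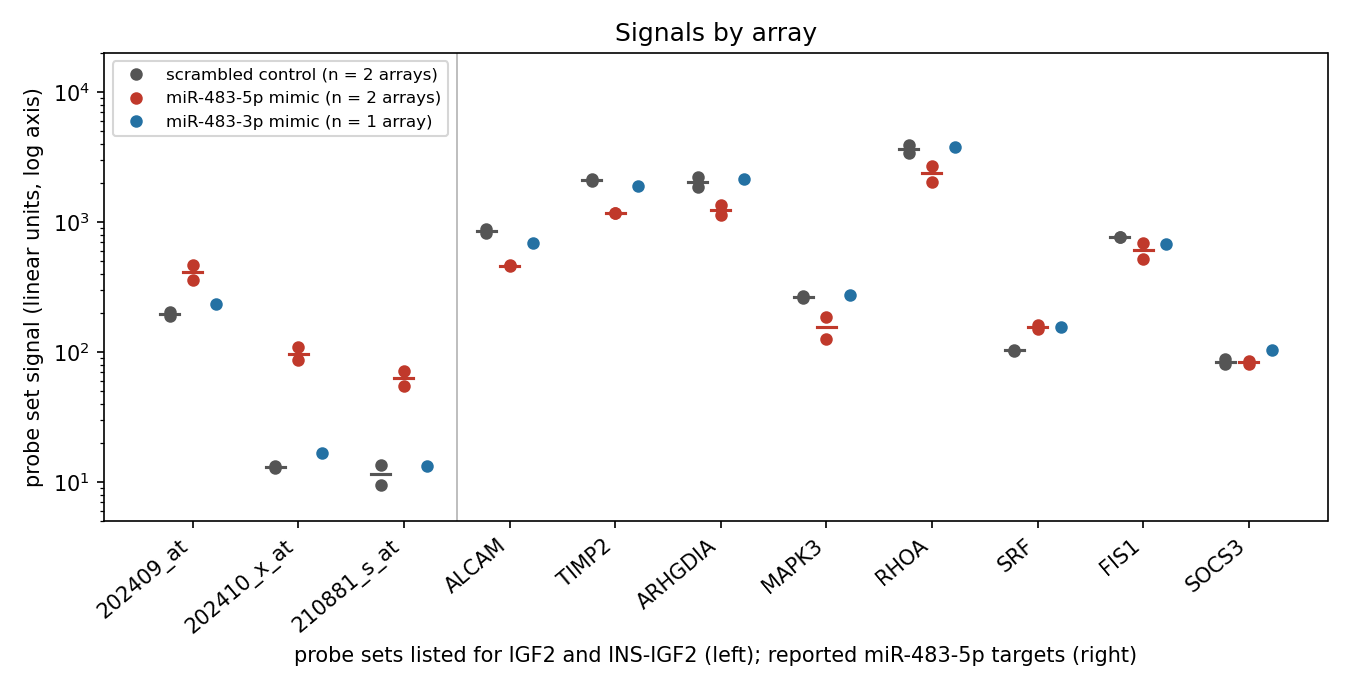
Probe set signals in linear units on a log axis, with a point for each array and a bar at the mean of each pair, for the 3 probe sets listed for IGF2 and INS-IGF2 and for the 8 reported miR-483-5p targets. In all 3 IGF2 probe sets both miR-483-5p arrays lie above the control arrays and the miR-483-3p array, and in ALCAM, TIMP2, ARHGDIA, MAPK3 and RHOA they lie below them.

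Cell cycle genes were higher with miR-483-5p, whereas the replication-dependent histone genes measured, 7 of 15 on the list, were lower. Of 30 genes active in G2 and M phase, 27 were higher than in the control, with a list median of 0.34 on the log2 scale. Of these, 6 rose when adjusted over the list alone, and none passed over all genes. They were CENPE and CENPF, which act at kinetochores, the spindle motor KIF11, the spindle pole gene ASPM, HMMR and the centrosomal kinase gene NEK2. CENPE had a signal of 378 ± 13.9 against 229 ± 4.6, and KIF11 had 1043 ± 133 against 657 ± 43.8 (SD, n = 2 each). Of 29 S phase genes, 25 were higher, with a median of 0.20, and none passed over the list alone or over all genes. RRM1, a subunit of ribonucleotide reductase, had the lowest p of that list and was higher by 0.53 on the log2 scale (SE 0.14), with 0.12 in a second probe set. The 2 dimmer probe sets of ASPM gave 0.08 and 0.17. All 7 replication-dependent histone genes measured were lower, with a median of -0.50, and 5 fell when adjusted over the list alone and none over all genes. Of the 15 on the list, 4 had no probe set of their own and 4 lay under the filter. The first control array minus the second had a median of 0.35 on the histone list and -0.18 on the S phase list, which is large beside both list medians. The histone median was -0.42 without the first control array and -0.72 without the second. H2AC6 had a signal of 334 ± 64.7 against 819 ± 216, H2BC12 had 713 ± 65.1 against 1062 ± 187, and H2BC5 had 377 ± 30.4 against 541 ± 35.8. The camera adjusted p-values were 6.10e-11 for the G2 and M list and 0.000158 for both the S phase and the histone list, and each of the 3 was lost at adjusted p = 0.869 with an estimated correlation. The estimates were 0.46 for G2 and M, 0.34 for S phase and 0.14 for histones, so the preset of 0.01 makes these p-values too small. When the same 4 arrays were split so that each side held 1 miR-483-5p and 1 control array, crossing first arrays with repeats, camera still called the G2 and M list at a median of 0.11 (adjusted p = 0.00838) and the S phase list at 0.11 (adjusted p = 0.0323). Without the first control array the S phase median was 0.15 and its adjusted p was 0.0750. The GAPDH ratio of 1.09 and 1.10 against 1.02 and 0.996 goes along with these 3 lists as well.

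Immediate early genes and targets of SRF moved both ways with miR-483-5p. Of 25 measured, 3 rose and 3 fell when adjusted over the list alone, none passed over all genes, and the list as a whole was not called (camera adjusted p = 0.930). The transcription factor genes KLF2, EGR1 and FOS fell by 1.64, 1.11 and 0.51 on the log2 scale. The matricellular genes CCN1 and CCN2 rose by 0.64 and 0.54, and SRF rose by 0.47. KLF2 had a signal of 172 ± 3.82 with miR-483-5p and 611 ± 112 in the control, although a second, dimmer KLF2 probe set differed by 0.08. EGR1 had 132 ± 3.25 against 324 ± 27.8, and its other 2 probe sets gave -0.49 and -0.18. In the IGF axis list, 17 of 24 genes were higher and 1 rose over the list alone (none over all genes), namely HMGA2, which encodes an architectural chromatin protein, at 546 ± 75.9 against 271 ± 32, although 3 dimmer probe sets gave log2 differences of 0.22, 0.14 and 0.53. The list median was 0.14, with camera adjusted p = 0.0587. In the list of microRNA machinery, the decapping enzyme gene DCP2 rose by 0.91 and the Argonaute gene AGO2 fell by 0.67 when adjusted over the list alone, with a list median of 0.18 and camera adjusted p = 0.171. That median came from the first miR-483-5p array and was -0.055 without it. With miR-483-3p, DCP2 and AGO2 differed from the same controls in the same directions, by 0.54 and -0.73. The RNA helicase gene DHX9 had a signal of 1822 ± 0.566 against 1479 ± 106 (adjusted p = 0.513), but its other 2 probe sets differed by -0.21 and -0.52.

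Single genes with the largest differences are given as values, since none of the 14591 genes passed limma's test with an adjusted p under 0.05 in the comparison of miR-483-5p with the control. The lowest adjusted p was 0.226. At an unadjusted p under 0.05 there were 1563 genes, 773 higher and 790 lower, where chance alone gives 729.55. Centring each array on its median instead gave 1469 such genes, 890 higher and 579 lower. Among the highest differences were GPR162, an orphan receptor gene, at 105 ± 18.3 against 19.7 ± 6.51, the MAX-binding repressor gene MXD3 at 96.7 ± 1.48 against 20 ± 5.09, and the spindle motor gene KIFC1 at 508 ± 1.20 against 198 ± 46.9. PI15, TTLL7, MYBL1, ARHGAP33, MIRLET7D, PRRT2 and PALM3 completed the 10 largest, with log2 differences from 1.23 for PI15 to 1.05 for PALM3. A second probe set gave -0.38 for MYBL1, -0.05 for PI15 and -0.01 for ARHGAP33, which was also 0.37 without the second control array and 1.89 without the first. The lowest, after KLF2, included DEFB124, SPAAR, RNA45SN5, TAMALIN, COL12A1 and CLN8-AS1, from -1.29 to -1.14, and the palmitoyltransferase gene ZDHHC9 at 55.3 ± 8.06 against 159 ± 22.8, with 0.48 in a dimmer probe set. With miR-483-5p, TAMALIN and COL12A1 had mean signals of 19 and 13.35, under the filter's 27.2, as had TTLL7 in the control, at 10.4. SPAAR was -0.44 without the first miR-483-5p array, RNA45SN5 -0.76 without the second, and DEFB124 -0.76 without the second control array. The arrays of the 2 groups did not overlap in 42.5% of genes, where chance gives 33.3%. The count of 0 depended on the settings, with 37 genes called after median centring, 33 with a pseudocount of 100 and 39 when the variance prior followed intensity. The 20 genes called under all 3, chosen after their values were seen, comprised 10 higher (GPR162, MXD3, KIFC1, PI15, MYBL1, PALM3, OPN3, ASPH, KLHL12 and HMGA2) and 10 lower (KLF2, H2AC6, ZDHHC9, EGR1, STK40, ADIPOR1, VAMP3, RHOB, CDC34 and AKT1S1).

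The second comparison asked what the 3p arm changes. It rests on a single miR-483-3p array, assumed to vary like the other groups. EGR1 had a signal of 84.0 in that array against 324 ± 27.8 (SD, n = 2) in the control, and KLF2 had 233 against 611 ± 112. Of the 25 immediate early genes and SRF targets, EGR1, KLF2 and PHLDA1 fell when adjusted over the list alone, by 1.61, 1.27 and 0.81 on the log2 scale, and none passed over all genes. The second, dimmer KLF2 probe set differed by 0.19 here, a dimmer EGR1 probe set by -0.48, and the mean of the PHLDA1 probe sets by 0.012. The list median was -0.17 and was -0.11 without the second control array. Camera called it lower (adjusted p = 0.000311, lost at adjusted p = 0.813 with an estimated correlation) and fry gave adjusted p = 0.0230. Replication-dependent histone genes had a median of -0.62 (-0.25 without the filter on dim genes), with 6 of 7 lower. Over the list alone 4 fell, namely H4C8, H2BC5, H2AC6 and H2BC12. All 30 G2 and M genes were higher, with a median of 0.22. The proliferation marker MKI67 had the lowest p of that list, at 610 against 394 ± 11.3. Of 29 S phase genes, 27 were higher, with a median of 0.28 (0.15 without the first control array). CDC45 had the lowest p there, at 325 against 210 ± 17.2, and PCNA had a larger log2 difference, at 3200 against 2114 ± 94.2. Neither list had a member that passed over the list alone. The GAPDH 3' to 5' ratio of the miR-483-3p array, 1.06, also lay above the 1.02 and 0.996 of the controls.

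Genes of cholesterol synthesis were higher in 17 of 19 cases with miR-483-3p, with a median of 0.32. The 2 miR-483-5p arrays differed from each other by as much on this list (0.32), and camera also called it when first arrays were set against repeats. INSIG1, a regulator of the pathway, had 1792 against 1114 ± 182 and the isomerase gene IDI1 had 2490 against 1660 ± 116, with log2 differences of 0.62, -0.14 and -0.13 in its other probe sets, and no member passed over the list alone. Genes of the ATF4 amino acid response had a median of 0.15, with 16 of 21 higher, among them ATF5 at 467 against 344 ± 5.02. Genes repressed by the Ewing sarcoma fusion EWSR1-FLI1 had a median of -0.15, with 16 of 22 lower, among them DKK1 at 54.0 against 96.0 ± 2.05 and COL1A1 at 1567 against 2195 ± 147. The dimmer probe sets of ATF5 gave -0.11 to 0.03, and those of COL1A1 gave -0.48 to 0.19. The camera adjusted p-values were 1.82e-06 for S phase, 6.17e-06 for cholesterol synthesis, 1.53e-05 for G2 and M phase, 0.000571 for histones, 0.00721 for the EWSR1-FLI1 repressed genes and 0.0144 for the ATF4 response, and each was lost at adjusted p = 0.813 with an estimated correlation. Without the first control array the ATF4 list had a median of 0.12 and adjusted p = 0.101, and the EWSR1-FLI1 repressed list kept a median of -0.16 with adjusted p = 0.0531. Of 5 reported miR-483-3p targets measured, EI24 and IGF1 rose by 0.56 and 0.55 when adjusted over the list alone (-0.51 in another IGF1 probe set), CTNNB1, SMAD4 and GDF3 did not pass, and the list median was 0.23 (camera adjusted p = 0.103). EI24 was also higher with miR-483-5p than in the control, by 0.49. The probe set of BBC3, another reported target, is shared with MIR3190 and MIR3191 and differed by 0.12 with miR-483-3p. The 3 IGF2 probe sets differed from the control by 0.23, 0.11 and 0.06 on the log2 scale, with adjusted p = 0.920, 0.977 and 0.987.

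No single gene passed limma's test for miR-483-3p against the control (lowest adjusted p = 0.278). At an unadjusted p under 0.05 there were 957 genes, 366 higher and 591 lower, where chance alone gives 729.55. Most of the excess of lower genes went with median centring, which gave 440 higher and 497 lower, and with the 60th percentile filter, which gave 347 and 359. MXD3 was the highest at 131 against 20 ± 5.09, followed by MAMDC4, PGC, PRELID3A, LOC286359, ARHGAP33, PALM3, DLK2, PRSS33 and MIGA2, with log2 differences from 1.28 to 1.10. TNFRSF12A, a TNF receptor family gene, was at 8.5 against 104 ± 79.1, and SLC17A4, WDR38, SPAAR, SPATC1, MGC15885, SUCLG2-DT, ACBD4 and H2BC9 differed by -1.42 to -1.29. In the single miR-483-3p array, SLC17A4, WDR38, SPATC1, MGC15885, SUCLG2-DT and ACBD4 had signals of 10 to 25.8. These and TNFRSF12A lay under the filter's 27.2, with no known distance from background. A second probe set gave -0.14 for ARHGAP33, -0.42 for PRSS33 and 0.63 for SUCLG2-DT. Without the first control array TNFRSF12A was at -0.99 and PRSS33 at 0.66, and without the second ARHGAP33 was at 0.40. Median centring gave 2 called genes, MXD3 and EGR1, and EGR1 alone was called with a pseudocount of 100 or an intensity trend.

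**Figure D2:**
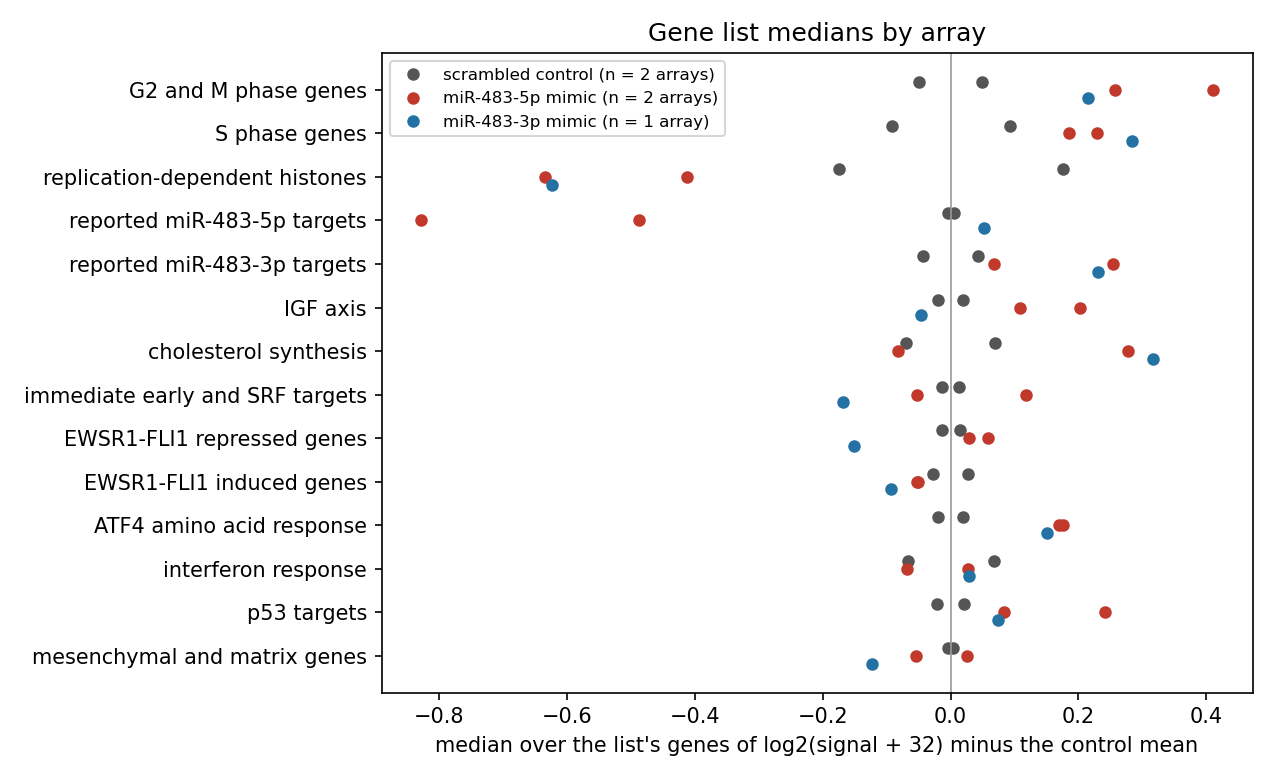
Median over the genes of each list of log2(signal + 32) minus the control mean, with a point for each of the 5 arrays. Both miR-483-5p arrays lie to the left of the controls for the reported miR-483-5p targets, where the miR-483-3p array lies at 0.05, and all 3 mimic arrays lie to the left for the histones and to the right for the G2 and M genes.

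The third comparison set the 2 arms against each other directly. The reported miR-483-5p targets were lower with the 5p arm than with the 3p arm, with a median of -0.60, and ALCAM, TIMP2, ARHGDIA, MAPK3 and RHOA fell when adjusted over the list alone, by 0.55, 0.66, 0.77, 0.73 and 0.68 on the log2 scale, although a dimmer TIMP2 probe set gave -0.13. The 3 IGF2 probe sets were higher with the 5p arm, by 0.72 (SE 0.21), 1.41 (SE 0.19) and 1.06 (SE 0.19), with adjusted p = 0.662, 0.536 and 0.536, and after median centring 202410_x_at passed (adjusted p = 0.0271). CCN1 was at 877 ± 12.3 (SD, n = 2) against 479 in the miR-483-3p array and rose in both the immediate early and the EWSR1-FLI1 repressed list, which share it, when adjusted over each list alone. HMGA2 was at 546 ± 75.9 against 205 and rose over the IGF axis list alone, but 2 of its dimmer probe sets gave -0.23 and 0.09. The adhesion gene L1CAM, of the neural list, was at 58.8 ± 4.95 against 6.80, and rose over its list alone. The list tests of this comparison were chosen after seeing the data. Camera called the 5p targets lower (adjusted p = 6.12e-05, and 0.493 with an estimated correlation), the immediate early list (median 0.22, adjusted p = 0.00137) and the EWSR1-FLI1 repressed genes (median 0.21, adjusted p = 0.00137) higher, both lost at adjusted p = 0.493 with an estimated correlation. Fry called the immediate early list alone (adjusted p = 0.0470). Camera also called the IGF axis higher (median 0.19, adjusted p = 0.00314), cholesterol synthesis lower (median -0.21, adjusted p = 0.00314) and G2 and M genes higher (median 0.14, adjusted p = 0.0442), each lost at adjusted p = 0.938 with an estimated correlation. The IGF axis call and the G2 and M call ended without the first miR-483-5p array, at adjusted p = 0.257 and 0.539, and the cholesterol call ended without the second, at adjusted p = 0.685. The IGF axis median was then still 0.17, while the G2 and M median shrank to 0.053 and the cholesterol median to -0.047, which was -0.40 without the first. The block for first arrays against repeats also ended the cholesterol and G2 and M calls, at medians of -0.089 and 0.13. Without the filter on dim genes the immediate early median was 0.11.

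No single gene differed between the arms by limma's test (lowest adjusted p = 0.564). There were 970 genes at an unadjusted p under 0.05, 497 higher and 473 lower with the 5p arm. TNFRSF12A, PIDD1, HHIP-AS1, WDR38 and GPR162 had the highest differences, from 1.87 to 1.42, and ANO7, TSNARE1, RANBP3, TINAGL1 and LINC01310 the lowest, from -1.65 to -1.18. In the miR-483-3p array TNFRSF12A, HHIP-AS1, WDR38 and GPR162 had signals of 8.5 to 25.1, under the filter's 27.2. With miR-483-5p, ANO7, TSNARE1 and TINAGL1 had mean signals of 12.95 to 24.1, also under it. The value for PIDD1 depended on which of its probe sets was used and was -0.16 with a pseudocount of 1. Other probe sets gave -0.45 to -0.12 for RANBP3 and -0.28 for TSNARE1. No control array enters this difference. Without the first control array RANBP3 and TSNARE1 were at these same -0.45 and -0.28, as another of their probe sets then had the highest mean. TINAGL1 was at -0.77 without the second miR-483-5p array. Median centring gave 7 called genes, which included GPR162, PIDD1, WDR38, ANO7 and TSNARE1.

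Several of these genes differed from the control in the same direction with both arms, KLF2, EGR1, H2AC6, MXD3, KIFC1 and PALM3 among them. Across genes, which are not independent replicates, the log2 differences of the 2 arms from the control correlated at Pearson's r = 0.457 and Spearman's rho = 0.450. Because both use the same control arrays, unchanged arrays were simulated in the same layout, with the shared controls simulated too. They gave a mean r of 0.409 (0.386 to 0.439 over 100 simulations). The covariance was 0.0310 against a simulated 0.0218, a difference of 0.00919. At an unadjusted p under 0.05, 280 genes passed in both with the same direction, 144 higher and 136 lower, where the simulations gave a mean of 154 (118 to 188) and independent lists 51.4. With a separate control array for each arm, which leaves 1 control on each side and none shared, r was 0.115 or 0.126. Shared controls alone gave the simulated mean of 154 against 51.4 for independent lists, so part of the excess is expected from them. The observed 280 genes and r = 0.457 lay above the simulated ranges. The simulated genes were independent of each other, which can make those ranges too narrow.

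**Figure D3:**
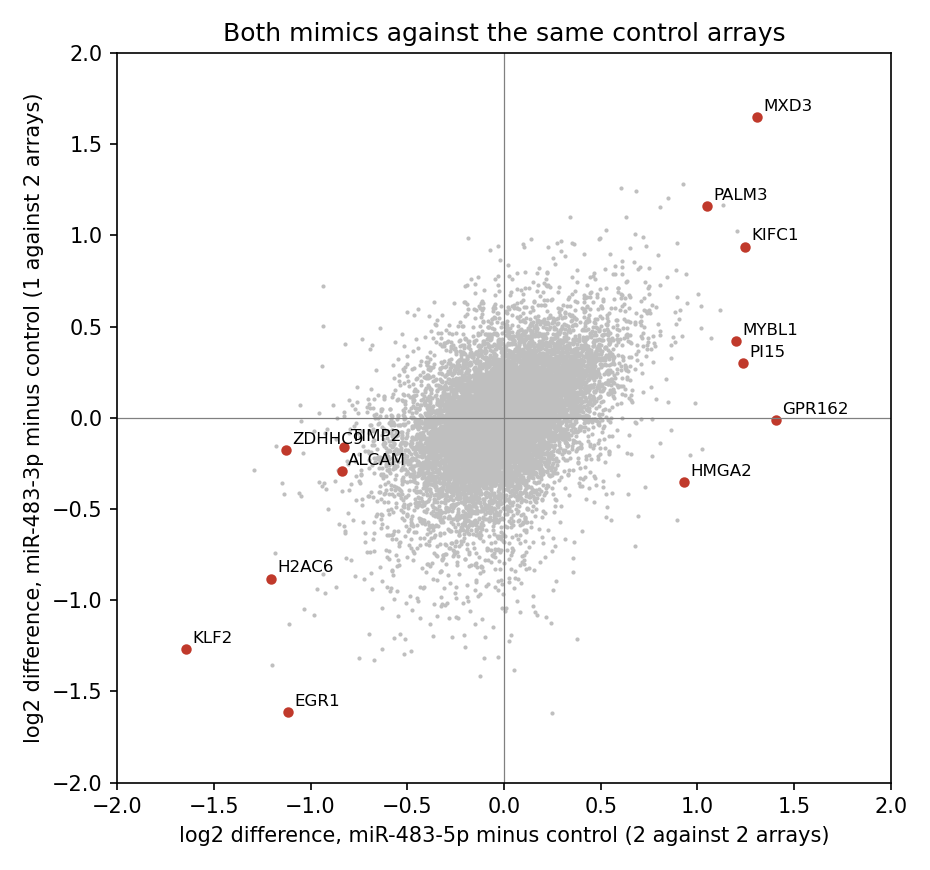
Log2 difference from the control for miR-483-5p (horizontal) and miR-483-3p (vertical), with a grey point for each of the 14591 genes tested and named genes in red. MXD3, KIFC1 and PALM3 lie at the upper right and KLF2, EGR1 and H2AC6 at the lower left, while GPR162 and ZDHHC9 lie near 0 on the vertical axis.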

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

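The block for first arrays against repeats and the list tests between the arms were chosen after seeing the data. The counts of called genes, 0 in each comparison, stayed at 0 with quantile normalization, no filter, a pseudocount of 1, the mean of a gene's probe sets, every probe set on its own, an adjusted p under 0.10, the block, and each paired array left out. Median centring called 37 genes for miR-483-5p, 2 for miR-483-3p and 7 between the arms; a pseudocount of 100 called 33, 1 and 0; a prior that follows intensity called 39, 1 and 0; and the 60th percentile filter called 1, 0 and 0. An unadjusted p under 0.05 with at least a 2-fold difference gave 31, 69 and 56. With the block, unadjusted p under 0.05 held for 2003, 1246 and 1387 genes. IGF2 probe sets 202409_at, 202410_x_at and 210881_s_at passed the threshold after median centring, at log2 differences of 0.98, 1.55 and 1.16; 202409_at and 202410_x_at passed with a pseudocount of 100 (0.78 and 0.80) and with the intensity trend (0.95 and 1.52), and 202410_x_at with the 60th percentile filter (1.52). Between the arms, 202410_x_at passed after median centring (1.40). The size of the IGF2 differences depended on the pseudocount, with 1.05, 2.80 and 2.37 at a pseudocount of 1 and 0.78, 0.80 and 0.55 at 100. Without a filter the histone median for miR-483-3p was -0.25 and the immediate early median between the arms 0.11, both still called. With arrays left out the differences of the 3 IGF2 probe sets from the control ran from 0.76 to 1.13, 1.39 to 1.64 and 1.0 to 1.25. The cause of the gained calls was not tested. The number of lists called by camera was 4 for miR-483-5p, 7 for miR-483-3p and 6 between the arms; the estimated correlation gave 0, 0 and 0, fry gave 0, 1 and 1, and leaving out arrays gave 6 to 11, 6 to 9 and 4 to 10, with 11 and 10 without the second miR-483-5p array and 7 for miR-483-5p without the first control. Of the alternative values of the medians of called lists, 125 kept their direction and their side of the threshold, 11 lost the call and 0 reversed. With the preset correlation, camera also called 6 lists when first arrays were set against repeats and 4 in the crossed split, so a call of it alone does not separate the mimic from the spread of these arrays. The block ended the ATF4 call for miR-483-3p (adjusted p = 0.0904) and the cholesterol and G2 and M calls between the arms (0.226 and 0.0530), and the last also ended with median centring and quantile normalization (0.0960 and 0.0511), although its median of 0.14 stayed about as large, at 0.13 with the block, 0.14 and 0.13. With the block the ATF4 median stayed at 0.14, from 0.15, and the cholesterol median shrank from -0.21 to -0.089. The correlation of both differences, 0.457, was 0.372 to 0.589 with arrays left out, the highest values being 0.589 and 0.580 without the first or second control, and 0.115 and 0.126 with separate controls. Of the alternative values of named genes, 1271 kept direction and side, 50 gained a call and 17 reversed. PIDD1 between the arms was -0.16 with a pseudocount of 1 and -0.17 to 1.59 with arrays left out, as another of its probe sets then had the highest mean. With the mean of probe sets, DHX9 was -0.14 against the control and -0.34 between the arms, SRF between the arms -0.15, SOCS3 0.14 for miR-483-5p, -0.050 for miR-483-3p and 0.19 between the arms, and PHLDA1 0.012 for miR-483-3p. SRF between the arms was -0.00101 with median centring and -0.044 to 0.046 with arrays left out, and SOCS3 for miR-483-5p was 0.025 with median centring, 0.022 with quantile normalization and -0.057 to 0.037 with arrays left out; the cause was not tested. Seed site tests were not run. The labels give no replicate number shared between groups, so the block for first arrays against repeats is the only pairing that was fitted. Depth does not apply to arrays, and without detection calls the dimmest signals named, under about the filter's 27.2, have no known distance from background.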

Other observations

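Tests of array scaling and of first arrays against repeats for IGF2, and of a response to the scrambled control for the reported targets, were chosen only after the result was seen. Of the 28 lists, those not described above were not called in any comparison by camera with the preset correlation over all 5 arrays. Fry's mixed test, which asks whether genes of a list change in either direction, gave adjusted p under 0.05 with miR-483-5p for 10 lists. The values were 0.000211 for EWSR1-FLI1 repressed genes, 0.0256 for the IGF axis, immediate early genes, reported miR-483-5p targets, EWSR1-FLI1 induced genes, mesenchymal and matrix genes and TGF-beta targets, 0.0314 for the ATF4 response and microRNA machinery, and 0.0327 for neural genes. It does not set a list against other genes. Genes of p53 response had a median of 0.14 with miR-483-5p (13 of 19 higher, camera adjusted p = 0.0587) and 0.07 with miR-483-3p, and cytosolic ribosomal protein genes had -0.10 (28 of 34 lower, adjusted p = 0.0587) and -0.01, while the 2 control arrays differed by -0.34 in the ribosomal list, whose median with miR-483-5p was 0.10 without the second. Genes induced by EWSR1-FLI1, the fusion that drives Ewing sarcoma, had medians of -0.10 and -0.09, with adjusted p = 0.417 and 0.507. Genes of interferon response, which double-stranded RNA can induce, had -0.02 and 0.03, with adjusted p = 0.922 and 0.513. The control arrays were also given a mimic, so an interferon response common to all mimics could not show in these comparisons. The medians of the 24 lists not called with miR-483-5p lay from -0.10 to 0.19, and of the 21 not called with miR-483-3p from -0.22 to 0.23. With 1 array left out, 15 and 10 of them changed sign, TGF-beta targets from 0.13 to -0.057 without the first miR-483-5p array among them, so no direction is given for these lists. With miR-483-3p, L1CAM and ELF3 fell when adjusted over the neural and the epithelial list alone, by 1.19 and 0.88, and neither passed over all genes. CSF1R, of the blood cell list, was lower with the 5p than the 3p arm by 0.86 over its list alone.

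The higher signal of the 3 IGF2 probe sets with miR-483-5p was weighed against technical explanations. A single array was argued against, since the smallest log2 difference with any of the 4 arrays left out was 0.760, and the scaling of the arrays was argued against by a smallest difference of 0.945 after median centring or quantile normalization. A difference between first arrays and repeats cancels in the group means, since each group holds 1 of each, and the smallest log2 difference within first arrays or within repeats was 0.712, where it would leave none. A candidate explanation is that miR-483-5p raises RNA from its host locus, which stays a hypothesis, since it was found on these arrays and the probe sets did not pass the threshold as fitted. Cross-hybridisation and the share of INS-IGF2 stay open and were not tested. The GAPDH 3' to 5' ratio, a sign of RNA integrity, was also higher in both miR-483-5p arrays than in both controls, and it stays open here too.

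The higher G2 and M genes with miR-483-5p may reflect a shift of dim or bright genes, but the list median lay at percentile 100 of random lists matched on mean expression. The smallest median with an array left out was 0.257, so no single array decided it, and the larger difference within a pair was 0.157, against 0.34 between groups, which is only just under the limit set for it. The crossed split, where the list was still called at 0.11, goes with part of the difference coming from the spread of the arrays. The miR-483-3p array also lay above the same controls on this list (median 0.22), and the arms differed by 0.14. Between the arms the S phase and histone medians were -0.036 and 0.078. A response to the scrambled sequence therefore stays open for these lists and was not tested. A change in cell cycle distribution through the mimic stays open as a hypothesis, since that distribution was not measured here. The lower histone genes were not weighed with the G2 and M genes.

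The lower reported targets with miR-483-5p were weighed against a brightness-dependent shift, where the median lay at percentile 0 of matched random lists. With each array left out the highest median was -0.487, so no single array decided it. A response to any mimic was not tested, since the control arrays were also given one and it is common to both groups by design. A response to the scrambled sequence itself stays open, since the comparison with the other arm (-0.605) rests on a single miR-483-3p array. Direct repression by the 5p arm is a candidate explanation and an untested hypothesis, since no sites were searched. The GAPDH 3' to 5' ratio, which was higher in both miR-483-5p arrays than in both controls, also stays open for this list.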
